A study of Homo sapiens with 6 samples.

How the data were processed

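Polyadenylated RNA of THP-1 macrophages was sequenced. THP-1 is an established human monocytic leukaemia line that is widely differentiated into macrophage-like cells. The 6 libraries fall into 3 groups of 2, and each group was read from the labels. The LPS group was treated with LPS, a bacterial cell wall component that primes macrophages. Its titles read Ath DMSO, and no label says whether DMSO, a solvent, was given. The LPS and nigericin group received LPS followed by nigericin, a potassium ionophore that activates the NLRP3 inflammasome. The METTL3-depleted group received the same treatments in cells depleted of METTL3, the catalytic subunit of the m6A methyltransferase of RNA. Per the labels' protocols, priming used 500 ng/mL LPS for 3 hours, nigericin was given at 20 µM for 60 to 90 minutes, and libraries were made with a strand-specific kit. The replicate numbers come from the sample titles. No source used here says that the replicates came from separate cultures. The p-values rest only on the spread between these samples, pooled across genes of like level, and that spread may be technical. A METTL3-depleted library without nigericin was not analysed here, so no interaction of depletion with nigericin was fitted.

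The deposited table holds variance-stabilised values on a log2 scale for 21017 genes, made by the authors from gene counts divided by a size factor per library. Per the submitters' processing notes, the authors used FastQC, Trimmomatic 0.39, STAR 2.5.2a, featureCounts of Subread and DESeq2, and the notes name the builds hg38 and GRCm38. The order of these steps, their settings, the gene annotation and the strand setting of the counting are not given in the sources used here. Values ran from 7.13, the shared value of a gene with no reads, to 21.3. Variance stabilisation compresses the changes of genes with few reads, so a log2 change given here understates the fold of a low gene.

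The stabilising function was inverted for each library, and 100% of the values gave whole reads within a tolerance of 1e-07. The largest deviation from a whole number was 5.6e-08. The recovered reads gave the depth of each library (44106204 to 58816764 reads), the size factors relative to each other, and folds in normalised reads, meaning reads divided by the size factor. Reads without molecular identifiers are not independent molecules. The chi-square per degree of freedom between the replicates of a group was 45.6, 32.4 and 7.17 in the LPS, the LPS and nigericin and the METTL3-depleted groups, so no pair differed by sampling noise alone, and all 6 libraries were counted.

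Tests were run in R 4.3.3 with limma 3.58.1. One linear model with a mean per group was fitted to all 6 libraries, which left 3 residual degrees of freedom, and empirical Bayes moderation used a mean-variance trend. The estimated prior degrees of freedom were infinite, so a gene's own replicate spread carried no weight in its p-value, and the 3 residual degrees of freedom did not limit it. Genes were kept when their mean over the 6 libraries lay at least 1 above the smallest value, which left 11183 genes. The 3 comparisons were LPS and nigericin minus LPS, METTL3-depleted minus control among cells given LPS and nigericin, and METTL3-depleted cells given LPS and nigericin minus LPS. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes kept and a call at an adjusted p under 0.05. With 2 libraries per group, no exact permutation test of a single value can reach that threshold, so no such test was run. Calls rest wholly on the variance that limma pooled across genes of like level.

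The design, 25 gene lists and the rule for named genes were set before the data were examined. The lists covered inflammasome and pyroptosis genes, the m6A machinery, inflammatory cytokines and chemokines, NF-kB feedback genes and targets, the type I interferon response, immediate early genes, the unfolded protein and integrated stress response, the heat shock response, the NRF2 oxidative stress response, metallothioneins, hypoxia and glycolysis, cholesterol biosynthesis, lysosome and autophagy, mitochondrially encoded transcripts, nuclear oxidative phosphorylation genes, ribosomal proteins, p53 targets, the cell cycle, macrophage differentiation, antigen presentation, apoptosis regulators, and ion and water transport. Markers of T and NK cells, of B cells, and of fibroblasts and epithelial cells formed the remaining lists. Lists with at least 5 tested members (23 of them) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and each call was repeated with an estimated correlation. The rule named METTL3 and 7 inflammasome genes in every comparison. It added the 12 largest rises and the 12 largest falls among called genes with non-overlapping groups and a mean at least 2 above the smallest value, and up to 4 members of each list with the smallest p. Clone-based names, pseudogenes, XIST and Y-linked genes were left out. Symbols are those of the deposited table, with the current symbol in brackets where it differs.

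The limma gene test and camera were tried on simulated reads drawn for the real genes with 200 genes changed. Of genes changed 1.5-fold, 44.8% were recovered for nigericin, 61.2% for METTL3 depletion and 64.2% for the comparison of METTL3-depleted nigericin cells with LPS. At 2-fold the shares were 95.5%, 92.5% and 94%, and false calls numbered 14, 15 and 13 among 11396, 11152 and 11395 tested genes. Simulated genes of like level had the same dispersion and varied independently, as the pooled variance assumes. These false calls therefore do not test that assumption in the real libraries. Coordinates, transcript lengths and GC contents come from GENCODE release 29 on GRCh38, which matched 17198 genes of the table and 97.5% of those tested. The release the authors used may differ.

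Alternatives set beforehand were a replicate block, no filter or a stricter filter (2 above the smallest value, 8119 genes), quantile normalization, a shift to equal medians, other variance moderation, a fit of the compared groups alone, and leaving out each library in turn. List tests were also run with fry. Alternatives chosen after seeing the data were each gene's own variance without moderation, voom on the recovered reads, scaling of recovered reads by their total with 0.5 reads added, and removal of a loess trend on GC content and transcript length. Total-count scaling asks about shares of all reads, while the deposited scaling centres on the typical gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.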

Results

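Transcript levels were measured by RNA-seq in 6 libraries of THP-1 macrophages, 2 each from cells given LPS, cells given LPS and nigericin, and METTL3-depleted cells given LPS and nigericin. The recovered depth was 51248242 and 58816764 reads in the LPS libraries, 52498308 and 44106204 in the LPS and nigericin libraries, and 49030568 and 49364369 in the METTL3-depleted libraries. Correlations across genes between the replicates of a group were 0.9906, 0.9951 and 0.998, where genes are not independent replicates. The size factors behind the deposited values differed between groups more than the depths did. Normalised totals, in units of 1e+06 reads, were 32.6 ± 3.08 (SD, n = 2) with LPS, 69.9 ± 3.85 with nigericin and 57.1 ± 1.56 with METTL3 depletion and nigericin. The 100 most abundant genes took 25.4% and 27.1% of the reads in the LPS libraries and 35% to 37.2% in the other libraries. The share of reads from mitochondrially encoded mRNA was 1.67% ± 0.17 (SD, n = 2) with LPS, 0.102% ± 0.00806 with nigericin and 0.0978% ± 0.00453 with depletion and nigericin. The median change of all genes (log2) was 0.0634 for nigericin, −0.0195 for METTL3 depletion and 0.0455 for their combination on the deposited scale, and −1.01, 0.263 and −0.746 when scaled by total reads. Changes below are on the deposited scale, relative to the typical gene.

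METTL3, on chromosome 14 from 21498133 to 21511375 (minus strand, GRCh38, protein coding), had 835 and 799 reads in the LPS libraries, 289 and 253 with nigericin, and 132 and 120 in the METTL3-depleted libraries. Its level fell by 0.78 ± 0.124 (log2, SE) in depleted against control cells under LPS and nigericin, to 0.372 of the normalised reads (limma, Benjamini-Hochberg adjusted p = 2.6e-08), and both depleted libraries lay below both controls. Against the LPS group the depleted cells were lower by a log2 change of −0.98 (limma adjusted p = 1.9e-14). Nigericin itself gave a METTL3 change of −0.20 ± 0.124, which did not pass (limma adjusted p = 0.135). That change passed when scaled by total reads (−1.4), after removal of a trend on GC content and transcript length (−0.239) and with each gene's own variance (−0.199). The call on depletion was lost with each gene's own variance.

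The first comparison asked what nigericin adds to LPS-primed macrophages. HSPA6, an inducible HSP70 chaperone, rose 1280-fold in normalised reads with nigericin. The neutrophil and monocyte attractants CXCL2 and CCL3 rose 67.2-fold and 106-fold, and FOSB, a subunit of the AP-1 transcription factor, rose 355-fold. Transcripts of the mitochondrial genome fell together, MT-CO1 to 0.0633 of its LPS level, and the interferon-induced IFIT3 fell to 0.0242. Of 11183 tested genes, 8468 changed, 4525 up and 3943 down, of which 2127 rose and 1014 fell by at least 1 on the log2 scale. With each gene's own variance in place of the one pooled across genes, 6764 genes were called, among them all 113 named genes with a call. The groups did not overlap in 84.5% of tested genes, against 33.3% by chance. When libraries were scaled by total reads, the split was 1793 up and 7742 down, with quantile normalization 46.8% of calls were up, and with the stricter filter 63% were.

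The largest rises also held C11orf96 (log2 8.10), PPP1R27 (7.09), G0S2 (6.40), an inhibitor of the lipase ATGL, and EPHA2 (5.67), an ephrin receptor kinase. HCAR2 (6.69) and HCAR3 (5.75) encode near-identical hydroxycarboxylic acid receptors, so their shares of reads are uncertain, and CCR7 (5.52) encodes the receptor for lymph node chemokines. CCL3 and HSPA1B (5.71) have near-identical copies as well. The largest falls besides MT-CO1 and IFIT3 included TDO2 (−3.81), a tryptophan dioxygenase, RCAN1 (−3.59), a calcineurin regulator, and ENG (−3.50), a TGF-beta co-receptor. MT-CO2 (−3.45), PCK2 (−3.28), the mitochondrial PEP carboxykinase, MT-ND6 (−3.27), IFIT1 (−3.21), IPCEF1 (−3.17) and SAMHD1 (−2.98), a dNTP hydrolase, followed. The SE of these changes was 0.128 to 0.192, and all passed in limma with Benjamini-Hochberg adjustment.

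Inflammatory cytokines and chemokines rose as a group with nigericin. Of 23 tested members 18 rose, 3 fell and 2 did not pass, the same numbers as adjusted over the list alone, and the median change was 3.26 (limma camera adjusted p = 2.3e-18, adjusted p = 0.1 with an estimated correlation). The growth factors CSF2 and CSF3 rose by log2 changes of 4.55 each. Of 21 NF-kB feedback genes and targets 19 rose and 2 fell, also adjusted over the list alone, among them the inhibitor NFKBIA (4.32), IER3 (4.02), the kinase IRAK2 (3.29) and TRAF1 (2.56) (limma camera adjusted p = 4.2e-08, adjusted p = 0.33 with an estimated correlation). Of 31 immediate early genes 25 rose and 4 fell, again adjusted over the list alone, with JUN at 4.47, the mRNA decay factor ZFP36 at 4.20 and the phosphatase DUSP1 at 3.99 (limma camera adjusted p = 5.3e-11, adjusted p = 0.38 with an estimated correlation). Heat shock genes rose in 14 of 18 cases and fell in 1, adjusted over the list alone too, with the co-chaperone DNAJB1 at 4.25 and HSPA1A at 3.52 (limma camera adjusted p = 1.9e-07, adjusted p = 0.31 with an estimated correlation). All 5 tested metallothioneins, metal-binding stress proteins, rose, with MT2A at 4.97 and MT1X at 4.25, and likewise adjusted over the list alone (limma camera adjusted p = 4.9e-10, adjusted p = 0.32 with an estimated correlation). Scaled by total reads the NF-kB median went from 1.93 to 0.881 and the heat shock median from 0.969 to 0.00475, and with quantile normalization they were 1.01 and 0.601 and the heat shock list was not called. The medians of the cytokine, immediate early and metallothionein lists stayed above 1 under the scalings by total reads and by quantiles.

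The type I interferon list moved the other way. Of 27 members 21 fell, 4 rose and 2 did not pass, the same adjusted over the list alone, with a median of −1.51 (limma camera adjusted p = 2.4e-09, adjusted p = 0.29 with an estimated correlation). The RNA sensor DDX58 (RIGI) fell by 2.86 on the log2 scale, while the exonuclease gene ISG20 rose by 2.61. All 13 mitochondrially encoded transcripts fell, also adjusted over the list alone, with MT-ND4 at −2.97 and a median of −2.43 (limma camera adjusted p = 1.1e-13, adjusted p = 0.33 with an estimated correlation). Nuclear genes for oxidative phosphorylation rose in 29 of 34 cases and fell in 2 (30 and 2 adjusted over the list alone), including NDUFA1 at 1.77 and COX6B1 at 1.84. Their list was called with a median of 0.761 (limma camera adjusted p = 0.0065, adjusted p = 0.48 with an estimated correlation), but scaled by total reads the median was −0.197, and the call was lost with quantile normalization and with the stricter filter. All 50 ribosomal protein genes rose, also adjusted over the list alone, with RPS16 at 2.46 and RPL38 at 2.24 and a median of 1.7, or 0.635 scaled by total reads and 0.285 with quantile normalization (limma camera adjusted p = 4.9e-10, adjusted p = 0.33 with an estimated correlation).

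Lysosome and autophagy genes rose in 32 of 40 cases and fell in 3, likewise adjusted over the list alone, among them TFEB, a master regulator of lysosomal genes (3.57), the proton pump subunit ATP6V0D2 (2.80), FNIP2 (2.86) and the galactosidase GLA (2.99). The list was called (limma camera adjusted p = 1.9e-06, adjusted p = 0.48 with an estimated correlation), and its median of 1.23 was 0.31 scaled by total reads and 0.438 with quantile normalization. Hypoxia and glycolysis genes rose in 21 of 30 cases and fell in 5, the same adjusted over the list alone, with the glucose transporter SLC2A1 at 3.62, PFKFB3 at 3.27 and ADM at 2.86 (limma camera adjusted p = 0.026, adjusted p = 0.72 with an estimated correlation). Cholesterol biosynthesis genes rose in 13 of 23 cases and fell in 1 (13 and 0 adjusted over the list alone), with the sterol sensor partner INSIG1 at 3.40, LSS at 2.61 and DHCR7 at 1.95 (limma camera adjusted p = 0.044, adjusted p = 0.48 with an estimated correlation). Scaled by total reads the medians of the latter 2 lists turned from 0.771 to −0.317 and from 0.393 to −0.626, and with quantile normalization the median of the former was −0.0382. Both calls were lost with quantile normalization and with the stricter filter.

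Inflammasome genes went both ways with nigericin. CASP1, the inflammatory caspase, rose by 1.29 ± 0.152 (log2, SE; limma adjusted p = 1.08e-16), but the change was 0.309 and did not pass when scaled by total reads. GSDMD, the pore-forming gasdermin, fell by 1.34 ± 0.143 (limma adjusted p = 4.92e-20). The adaptor PYCARD fell by 0.65 ± 0.13 (limma adjusted p = 1.39e-06) and the cytokine IL18 by 0.61 ± 0.119 (limma adjusted p = 6.12e-07). IL1B fell by 0.48 ± 0.193 (limma adjusted p = 0.0193). That call was lost without LPS and nigericin replicate 2 (−0.333), without either METTL3-depleted library (−0.475) and when only the groups compared were fitted. NLRP3, the sensor (−0.09 ± 0.154, limma adjusted p = 0.596), and its partner kinase NEK7 (−0.14 ± 0.13, limma adjusted p = 0.327) did not pass, whereas scaled by total reads both passed with changes of −1.2 and −1.3. NLRP3 also passed with quantile normalization (−0.749) and after removal of the GC and length trend (−0.278). Over the 23 tested members of the wider list 8 rose, 10 fell and 5 did not pass, the same adjusted over the list alone. The cell rupture gene NINJ1 rose by 2.64, DFNA5 (GSDME) by 2.07 and CARD16 by 1.91, while NLRX1 fell by 1.67, and the list as a whole did not pass (limma camera adjusted p = 0.62). The fold of CARD16 in normalised reads was 5.94, but 8 without LPS and nigericin replicate 1 and 3.88 without LPS and nigericin replicate 2.

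**Figure D1:**
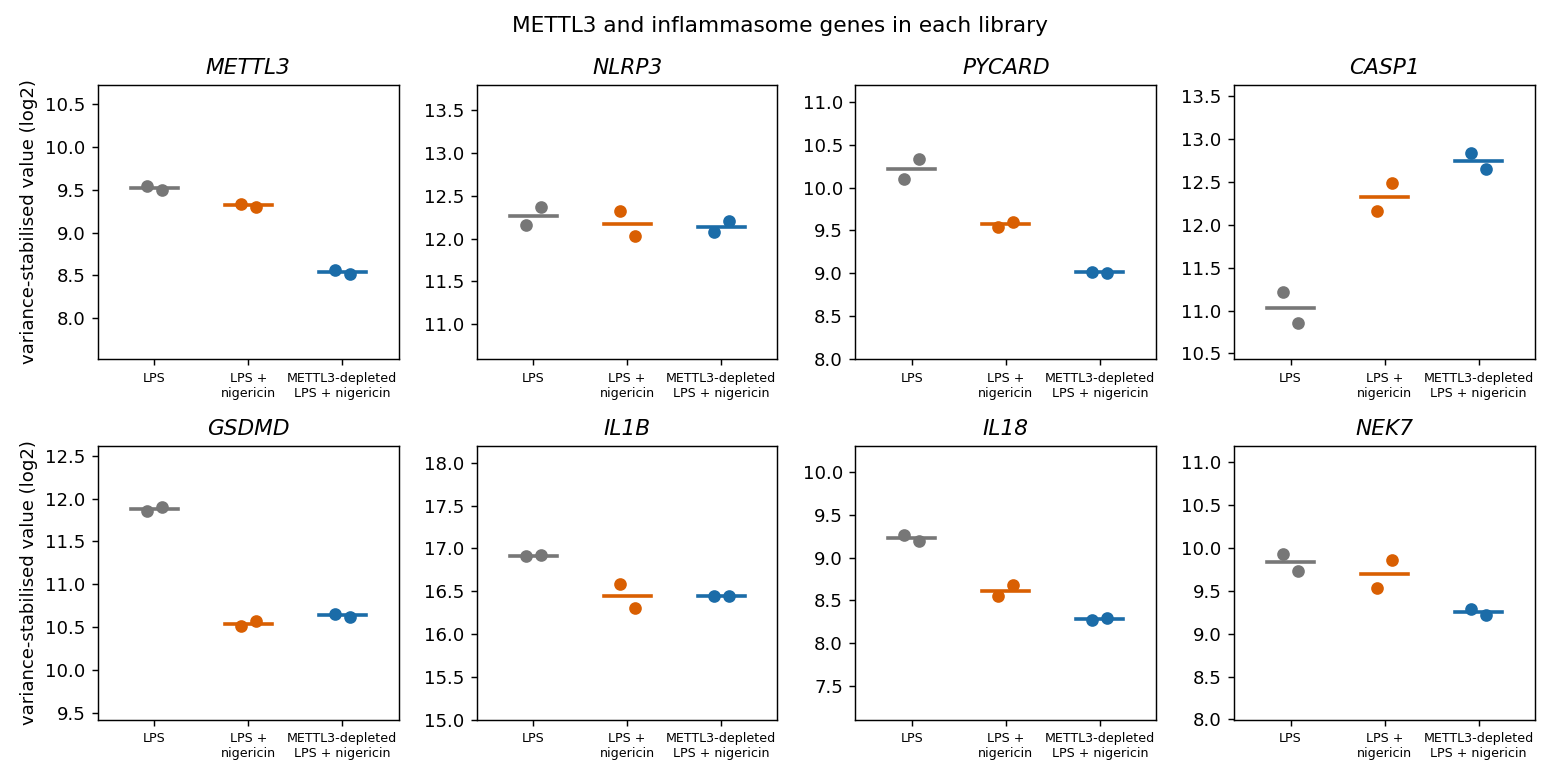
Deposited variance-stabilised value (log2) of METTL3 and 7 inflammasome genes in each of the 6 libraries. Points are libraries, horizontal lines are group means, and every panel spans the same height; both METTL3-depleted libraries lie below all others for METTL3, and CASP1 is lowest in the LPS group.

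The second comparison asked what METTL3 depletion changes in cells given LPS and nigericin. The sample titles name both depleted libraries M3sh1 and the controls Ath and spell out neither, so the nature of the control is unclear, and with this lone designation other effects of the depletion method are not separated here from the loss of METTL3. Depletion lowered LSP1, an actin-binding protein of leukocytes, to 0.276 of its control level in normalised reads, and lowered the nucleoside transporters SLC29A1 and SLC29A3 to 0.354 and 0.324. It raised SRSF5, a splicing factor, 2.90-fold, WSB1, a ubiquitin ligase substrate receptor, 2.72-fold, DNASE1L3, an extracellular nuclease, 3.49-fold, and the nuclear long noncoding RNA NEAT1 2.43-fold. The folds of SRSF5 and NEAT1 were 1.99 and 1.70 without LPS and nigericin replicate 1, and 5.34 and 4.30 without LPS and nigericin replicate 2. The lists of ribosomal proteins, nuclear oxidative phosphorylation, hypoxia and glycolysis, and the cell cycle were called lower by limma camera, though many members did not pass, and none was called with an estimated correlation (adjusted p = 0.98 with an estimated correlation for each). Of 11183 tested genes 3577 changed, 1385 up and 2192 down, and only 25 rose and 75 fell by at least 1 on the log2 scale. The groups did not overlap in 69.2% of genes, against 33.3% by chance. All depletion calls rest on variance pooled across genes. With each gene's own variance, at 3 residual degrees of freedom, limma called 0 genes after Benjamini-Hochberg adjustment, METTL3 included (lowest adjusted p = 0.0942), and 3189 at an unadjusted p under 0.05. Scaled by total reads the split was 3100 up and 973 down, and after removal of the GC and length trend it was 1714 up and 1794 down. The count was 769 without METTL3-depleted replicate 1, 1448 without METTL3-depleted replicate 2, and 2387 without LPS and nigericin replicate 1.

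The largest rises further included CCDC30 (log2 1.21), ZMYND11 (1.17), a reader of methylated histone H3.3, SERPINB7 (1.17), GOLGA8A (1.15), a member of a family of near-identical copies, and RSAD2 (1.14), the antiviral enzyme viperin. The noncoding PAX8-AS1 (1.12) and MIR22HG (1.07) were also among them, and the former lies antisense to another gene while the strand setting of the counting is not given. The largest falls held GPC3 (−1.33), a glypican, S100A4 (−1.30), a calcium-binding protein, and the actin regulators CAPG (−1.29) and COTL1 (−1.29). GAMT (−1.28), an enzyme of creatine synthesis, IDH2 (−1.28), the mitochondrial isocitrate dehydrogenase, MYBL2 (−1.25), a cell cycle transcription factor, CHI3L2 (−1.25), a chitinase-like protein, and CALM3 (−1.24), a calmodulin gene, followed. The SE of these changes was 0.125 to 0.185, and all passed in limma with Benjamini-Hochberg adjustment. NEAT1 lost its call under robust variance moderation.

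Ribosomal protein genes fell in 33 of 50 cases on depletion and rose in none (35 and 0 adjusted over the list alone), with RPS9 at −1.03, RPL35 at −0.94 and RPSA at −0.93. The list median was −0.551 (limma camera adjusted p = 2.8e-08, adjusted p = 0.98 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 18 of 34 cases and rose in none, also adjusted over the list alone, with COX5B at −1.03, UQCRC1 at −0.95, COX6B1 at −0.89 and NDUFV1 at −0.87 (limma camera adjusted p = 6e-05, adjusted p = 0.98 with an estimated correlation). Of 30 hypoxia and glycolysis genes 17 fell and 2 rose (18 and 2 adjusted over the list alone). The glycolytic enzymes GPI, TPI1, PKM and GAPDH changed by −1.13, −1.02, −1.03 and −1.03 (limma camera adjusted p = 0.00028 for the list, adjusted p = 0.98 with an estimated correlation). Of 29 cell cycle genes 17 fell and 2 rose (18 and 2 adjusted over the list alone), with the transcription factor E2F1 at −1.17, MCM2 at −0.90, CDC20 at −0.88 and BIRC5 at −0.83 (limma camera adjusted p = 1.4e-05, adjusted p = 0.98 with an estimated correlation). In the same order, the medians of these 4 lists were −0.551, −0.388, −0.49 and −0.444, became −0.262, −0.116, −0.238 and −0.258 scaled by total reads, and −0.154, −0.185, −0.254 and −0.395 with quantile normalization. The lists kept their camera calls at the preset correlation after removal of the GC and length trend.

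Of 25 macrophage differentiation genes 10 fell, 2 rose and 13 did not pass (11 and 2 adjusted over the list alone). The lipoprotein genes APOE (−1.21) and APOC1 (−0.74), the scavenger receptor MARCO (−0.72) and the growth factor receptor CSF1R (−0.76) fell (limma camera adjusted p = 0.043 for the list, adjusted p = 0.98 with an estimated correlation). The list median of −0.323 was −0.0669 scaled by total reads and −0.114 with quantile normalization. That list call was lost after removal of the GC and length trend, with quantile normalization and with the stricter filter. CSF1R was not called without METTL3-depleted replicate 1 (−0.751), and APOC1 not when scaled by total reads (−0.505). Cytokine genes went both ways, with 6 up, 6 down and 11 of 23 not passing (8 and 6 adjusted over the list alone). IL36G rose by 0.97, CXCL3 by 0.68 and CSF3 by 0.61, while CCL5 fell by 0.85, and the list did not pass (limma camera adjusted p = 0.39) except, upward, with quantile normalization. CCL5 was not called without METTL3-depleted replicate 1 (−0.802), nor were CXCL3 (0.584) and CSF3 (0.566) without METTL3-depleted replicate 2.

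Lysosome and autophagy genes fell in 10 of 40 cases and rose in 4, the same adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.44), with a median of −0.147 that became 0.126 when scaled by total reads and 0.0901 with quantile normalization. MAP1LC3A fell by 1.00 and TFEB by 0.99, GAA by 0.75 and ATP6V0D1 by 0.78, and the latter 2 were not called without METTL3-depleted replicate 1 (−0.648 and −0.719). The m6A machinery held 21 tested genes, of which METTL3 fell and KIAA1429 (VIRMA), a scaffold of the writer complex, rose by 0.40, while only METTL3 passed adjusted over the list alone (limma camera adjusted p = 0.39). The list was called, upward, with quantile normalization. KIAA1429 lost its call without any of the libraries LPS and nigericin replicate 2 (0.231), METTL3-depleted replicate 1 (0.374) or replicate 2 (0.419), and without a filter, with quantile normalization and after removal of the GC and length trend. The readers YTHDF1 (0.35) and YTHDF2 (0.33) did not pass. Both passed without LPS and nigericin replicate 1 (0.483 and 0.472), without either LPS library (0.347 and 0.328), when only the groups compared were fitted, when scaled by total reads, with quantile normalization and after removal of the GC and length trend.

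Among inflammasome genes, NLRP3 (−0.04 ± 0.154, limma adjusted p = 0.871), IL1B (0.00 ± 0.193, limma adjusted p = 0.991) and GSDMD (0.10 ± 0.143, limma adjusted p = 0.633) did not pass on depletion. PYCARD fell by 0.56 ± 0.13 (limma adjusted p = 0.000197) and the call was lost after removal of the GC and length trend (−0.185). NEK7 fell by 0.45 ± 0.13 (limma adjusted p = 0.00359) and IL18 by 0.33 ± 0.119 (limma adjusted p = 0.0217). CASP1 rose by 0.42 ± 0.152 (limma adjusted p = 0.0215). The calls of NEK7 and IL18 were lost without LPS and nigericin replicate 2 (−0.284 and −0.268), without METTL3-depleted replicate 1 (−0.48 and −0.32) and without METTL3-depleted replicate 2 (−0.414 and −0.344), and when scaled by total reads. The call of CASP1 was lost without LPS and nigericin replicate 1 (0.258) and without METTL3-depleted replicate 1 (0.325) or replicate 2 (0.521). None of PYCARD, NEK7, IL18 and CASP1 was called with each gene's own variance. GSDMD passed when scaled by total reads (0.409) and after removal of the GC and length trend (0.341), and IL1B passed with quantile normalization (0.433). Over the wider list 3 genes rose, 4 fell and 16 did not pass (4 and 5 adjusted over the list alone; limma camera adjusted p = 0.91).

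**Figure D2:**
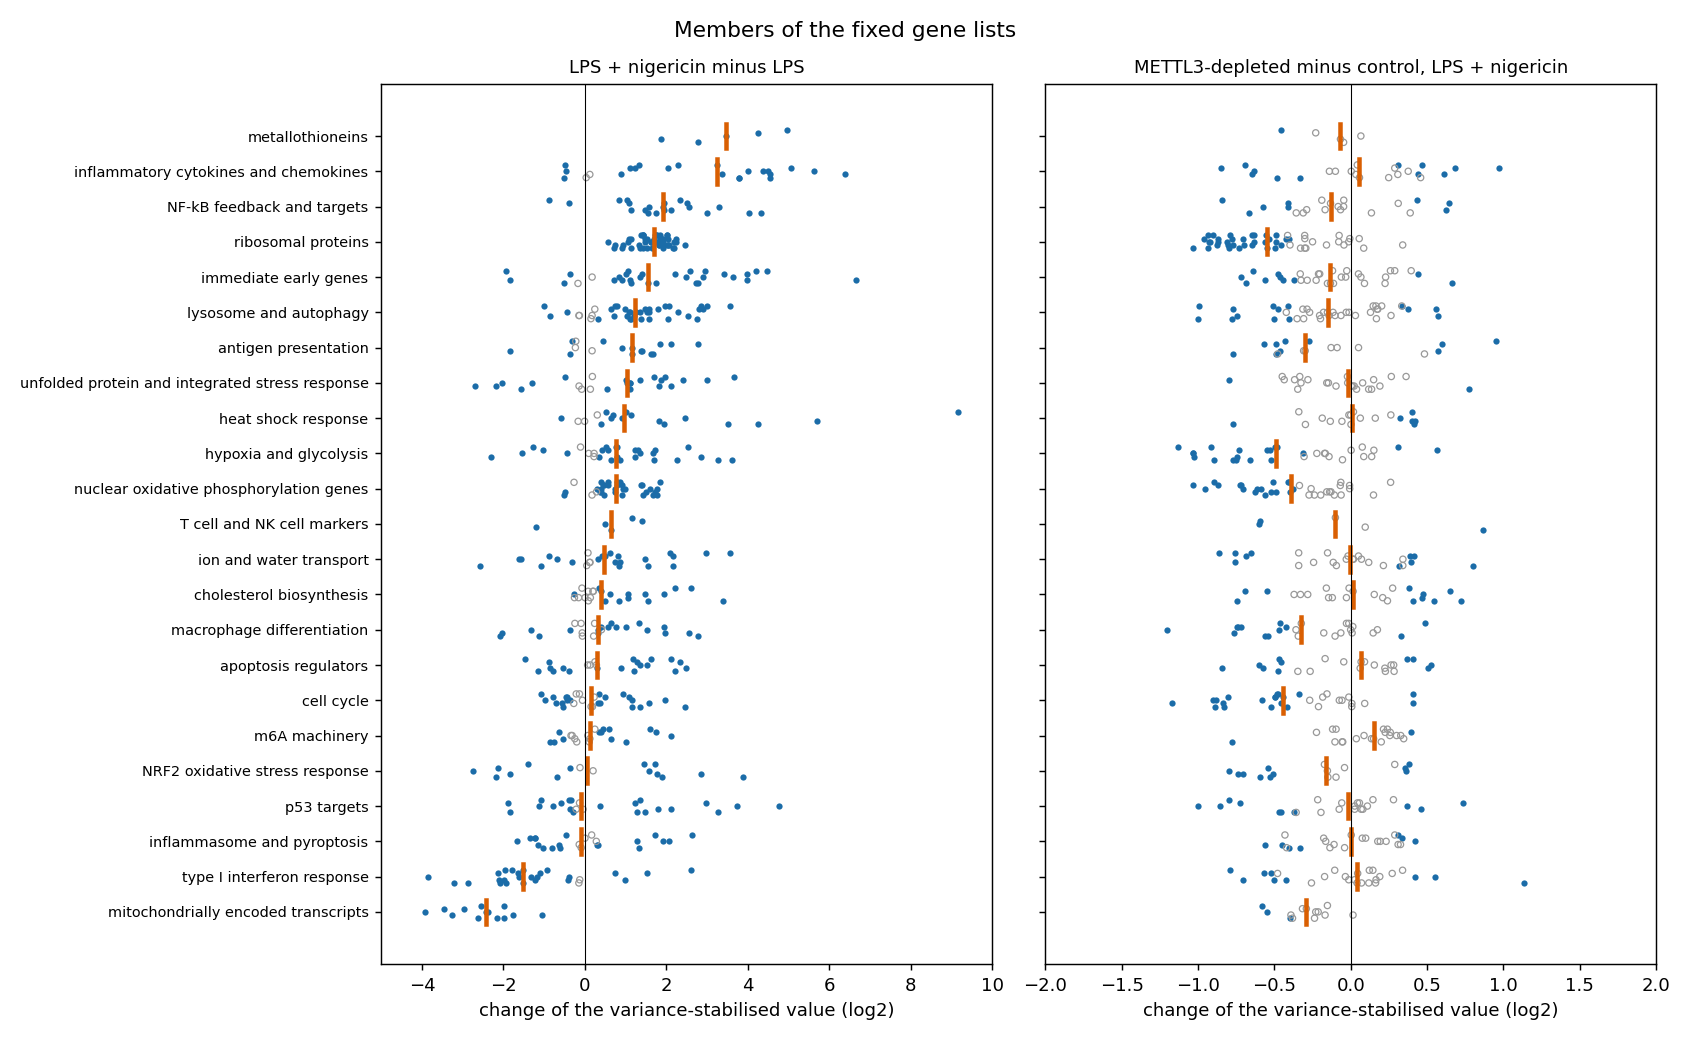
Changes (log2) of the members of 23 fixed gene lists with nigericin (left) and on METTL3 depletion (right), with separate scales. Filled points passed at an adjusted p under 0.05, open points did not, and vertical bars are list medians; ribosomal protein genes have medians of 1.7 and −0.551, which became 0.635 and −0.262 when scaled by total reads.

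Depleted cells given LPS and nigericin were also set against the LPS group. The leading genes were largely those of the nigericin comparison, with HSPA6 at log2 8.82, C11orf96 at 7.71, FOSB at 6.09 and CXCL2 at 6.01. IL23A, a subunit of interleukin 23, rose 41.2-fold in normalised reads. The largest falls included MT-CO1 (−4.13), ENG (−4.11), the actin regulator CORO1A (−3.33) and the signalling regulator RGS16 (−3.30). IL23A, CORO1A and RGS16 also moved in these directions with nigericin in control cells. Before division by size factors, IL23A had 28373 and 23158 reads with LPS and 394845 and 317874 with nigericin. CORO1A had 34129 and 40027 against 3687 and 3034, and RGS16 150963 and 182259 against 12623 and 10600. Of 11183 genes 8263 changed (limma, Benjamini-Hochberg), 4353 up and 3910 down, with 1763 up and 1036 down by at least 1, and 86.4% of genes had no overlap against 33.3% by chance. Scaled by total reads the split was 1984 up and 6927 down, and with each gene's own variance 6405 genes were called, NEK7 no longer among them.

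PYCARD fell by 1.21 ± 0.13 (limma adjusted p = 9.46e-20), GSDMD by 1.24 ± 0.143 (limma adjusted p = 2.45e-17), IL18 by 0.95 ± 0.119 (limma adjusted p = 1.15e-14) and NEK7 by 0.59 ± 0.13 (limma adjusted p = 1.33e-05) in this comparison. CASP1 rose by 1.71 ± 0.152 (limma adjusted p = 2.35e-28). IL1B fell by 0.47 ± 0.193 (limma adjusted p = 0.021), a call lost without METTL3-depleted replicate 1 (−0.463) or replicate 2 (−0.479). NLRP3 did not pass (−0.13 ± 0.154, limma adjusted p = 0.443), but passed when scaled by total reads (−0.949). Of 23 lists 10 were called by limma camera, 8 up and 2 down, and none with an estimated correlation, where adjusted p was 0.079 to 0.56 for the 10 lists. Cytokines (19 up, 2 down of 23), immediate early genes (25 up, 4 down of 31), heat shock genes (16 up, 1 down of 18), ribosomal proteins (50 of 50 up) and all 5 metallothioneins rose, and 21 of 27 interferon genes and all 13 mitochondrially encoded transcripts fell, the same counts as adjusted over the list alone. Hypoxia and glycolysis (12 up, 7 down of 30) and nuclear oxidative phosphorylation genes (19 up, 3 down of 34) did not pass as lists (limma camera adjusted p = 0.31 and 0.22), though the latter passed without a filter. The ribosomal and cholesterol calls were lost with quantile normalization.

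The nigericin and depletion changes were set against each other gene by gene, since genes moved by nigericin may lie nearer to their LPS level after depletion. Of 2782 genes called in both comparisons with the pooled variance, 2067 changed on depletion in the direction of the LPS level. The other 715 moved further from it (25.7%, exact 95% binomial interval 24.1% to 27.4%, in which genes are not independent). These counts pair signs and measure no distance. A gene among the 2067 may have passed its LPS level and ended further from it on the other side. Genes up with nigericin and down on depletion numbered 1427, and genes down and then up 640, where independent lists would give 887 and 488. Genes up in both numbered 366, and genes down in both 349, against 560 and 773 for independent lists. The comparisons share the LPS and nigericin libraries with opposite signs, which by itself raises the first pair of counts. TFEB, MCM2 and E2F1 rose with nigericin (3.57, 1.97 and 1.57) and fell on depletion (−0.99, −0.90 and −1.17), whereas AQP9, a water and glycerol channel, rose in both (2.15 and 0.80). The correlation of the changes across genes was −0.308 (Spearman −0.31). Unchanged groups that share the LPS and nigericin libraries gave −0.5 in 1000 simulations, a value that the sharing fixes for groups of equal size. The covariance was −0.112, against a simulated −0.00953 ± 0.000205 (SD), a difference of −0.103. The simulated noise was independent between genes, so that SD leaves out deviations that many genes of a library share and is too small to judge the difference by. With a separate LPS and nigericin library for each comparison the covariance was −0.0913 and −0.112, and with quantile normalization the difference was −0.0351.

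**Figure D3:**
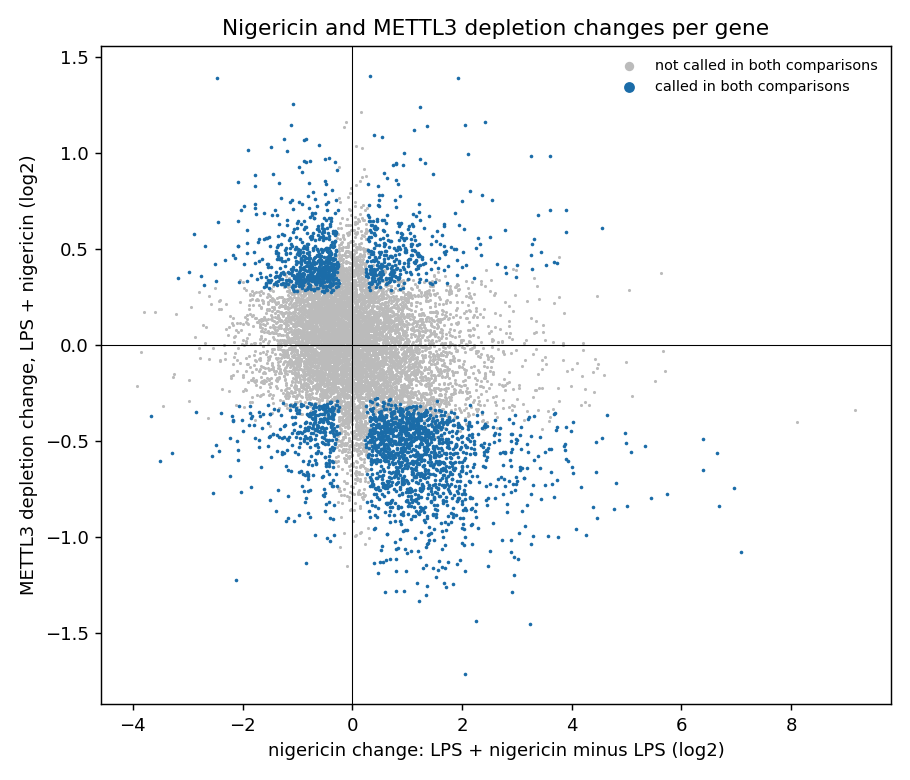
Nigericin change (x axis, log2) against METTL3 depletion change (y axis, log2) for 11183 genes. Each point is a gene and the 2782 genes called in both comparisons are coloured; 1427 of these lie at the lower right and 640 at the upper left, and the shared LPS and nigericin libraries alone tilt such a plot downward.

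Markers of other cell types differed between libraries. T and NK cell markers summed to 450 and 428 reads per 1e+06 reads with LPS, 273 and 318 with nigericin and 245 and 261 with depletion, most of them GNLY reads. B cell markers summed to 16.5 and 18.3, 74.8 and 89.4, and 101 and 92.9 per 1e+06 reads, mostly CD22, which rose with nigericin by 3.16 on the log2 scale. Fibroblast and epithelial markers summed to 62.2 and 65 with LPS and to 7.68 to 11.8 in the other libraries, and COL1A1 fell by 1.67 with nigericin. LPS and nigericin replicate 2 stood apart for a few genes. It held 137 IGHM reads and 70 MS4A1 reads, both B cell genes, where every other library held 0 to 4, and only 15 reads of HLA-F, where the others held 559 to 752. The HLA-F change on depletion (0.95) had an SE of 0.128 from the pooled variance, while the SD of its value between the LPS and nigericin libraries was 1.8. Without this library 7964 genes changed with nigericin and 2885 on depletion.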

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

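Each gene's own variance, voom on recovered reads, total-count scaling and the GC and length correction were chosen after seeing the data, and all other settings beforehand. Of 5960 recomputed values of named genes, 5678 kept their direction and their side of the threshold, 21 were called in neither setting and changed sign, 224 lost a call, 35 gained one and 2 called values changed sign, and the cause was not tested except where stated. CD3D with nigericin became −0.216 under the GC and length correction. HLA-F on depletion ranged from −0.326 without LPS and nigericin replicate 2, whose 15 reads set the change, to 2.23 without LPS and nigericin replicate 1. Named genes were mostly chosen for large changes or small p in these data, so other calls may hold less well. Of 8468 nigericin calls, total-count scaling called 1153 in the opposite direction and quantile normalization 229. The GC and length correction reversed 92 of 8257. In the combined comparison these settings reversed 401, 108 and 6 calls, and on depletion none. Counts of changed genes stayed within 1.5 times of the reported ones, apart from depletion with each gene's own variance (0) and with single libraries left out (769 to 4321), where a lone library is assumed to vary like the other groups and fewer samples remain. Leaving out libraries moved single genes as follows: on depletion CASP1 0.258 to 0.587, IL18 −0.395 to −0.268 and NEK7 −0.61 to −0.284, and IL1B −0.617 to −0.333 with nigericin and −0.479 to −0.463 for METTL3-depleted nigericin against LPS.

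With each gene's own variance, in a fit that leaves the changes as they were, METTL3 with nigericin (−0.199) gained a call, and METTL3 (−0.777), PYCARD (−0.56), NEK7 (−0.447), CASP1 (0.423) and IL18 (−0.332) on depletion and NEK7 in the combined comparison (−0.585) lost theirs. All 106 named genes called on depletion lost their calls, against 0 of 113 with nigericin and 1 of 117 in the combined comparison.

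For nigericin, quantile normalization gave NLRP3 −0.749, total-count scaling gave METTL3 −1.4, NLRP3 −1.2, NEK7 −1.3 and CASP1 0.309, and the GC and length correction gave METTL3 −0.239 and NLRP3 −0.278. IL1B stayed at −0.475 but lost its call when only the 2 groups were fitted, a fit with fewer samples. On depletion, without a filter CASP1 (0.423) and IL18 (−0.332) lost their calls among more tested genes, and quantile normalization gave IL1B 0.433. Total-count scaling gave GSDMD 0.409, IL18 −0.487 and NEK7 −0.372, and the GC and length correction gave PYCARD −0.185 and GSDMD 0.341. For the combined comparison NLRP3 was −0.664 with quantile normalization, −0.949 with total-count scaling and −0.289 with the GC and length correction. Camera with an estimated correlation called 0 lists in each comparison, and fry called 22 with nigericin, 0 on depletion and 19 in the combined comparison.

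With the replicate number as a block 8301, 3175 and 8085 genes were called. Correlations of same-numbered deviations were −0.372 (LPS with LPS and nigericin), 0.312 (LPS with METTL3-depleted) and −0.202 (LPS and nigericin with METTL3-depleted). With 2 replicates the deviations of a group mirror each other, so the sign follows the numbering. Exchanging the numbers of the LPS and nigericin libraries would make all of these correlations positive. They therefore do not show whether libraries of different groups share a factor, and the block covers only pairing by number. Between 552 and 2505 genes per library had no reads, a number that did not follow depth: LPS replicate 1 (51248242 reads) had 552 and LPS and nigericin replicate 1 (52498308 reads) had 2505.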

Other observations

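Tests of whole causes (2360 and 715 genes) and the GC test on the compared groups alone were chosen after the result was seen, and the list around splicing after the leading genes were seen, with those genes left out. Its version without MALAT1 and OGT was chosen later still. The other tests had bounds set before their values were computed, except that the condition on the interval of the share 0.257 was added after that share was seen.

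Stress, death and transport genes not described above also moved with nigericin. Of 24 p53 targets 11 rose and 10 fell, the same adjusted over the list alone, with PLK3 at 4.77, GDF15, a stress cytokine, at 3.75, AEN at 3.27 and the BH3 gene BBC3 at 2.98, and the list did not pass (limma camera adjusted p = 0.24). Its median (−0.087) and its mean (0.639) differ in sign. Unfolded protein and integrated stress genes rose in 15 of 25 cases and fell in 6, also adjusted over the list alone: the phosphatase subunit PPP1R15A rose by 3.65 and SDF2L1 by 3.00, while CHAC1 fell by 2.69 and the cystine transporter SLC7A11 by 2.17 (limma camera adjusted p = 0.24). NRF2 genes split 7 to 7 of 16, also adjusted over the list alone, with HMOX1 up by 3.89 and GCLM and ME1 down by 2.75 and 2.13 (limma camera adjusted p = 0.73), and its median (0.0414) was above 0 while camera gave the direction down. Apoptosis regulators rose in 12 of 23 cases and fell in 7, again adjusted over the list alone, with the survival genes CFLAR (2.49), BCL2A1 (2.34), BCL2 (2.21) and BIRC3 (2.11) up (limma camera adjusted p = 0.23). Of 26 ion and water transport genes 15 rose and 7 fell, likewise adjusted over the list alone. The inositol transporter SLC5A3 rose by 3.57, and the potassium channel gene KCNJ2 fell from 1345 and 1378 reads to 3 and 8 (limma camera adjusted p = 0.39). Of 17 antigen presentation genes 11 rose and 3 fell (limma camera adjusted p = 0.099), of 25 macrophage genes 13 rose and 5 fell with CD14 down by 2.09 (limma camera adjusted p = 0.52), of 29 cell cycle genes 12 rose and 10 fell (limma camera adjusted p = 0.73), and of 21 m6A genes 9 rose and 4 fell with WTAP up by 2.11 (limma camera adjusted p = 0.75), all the same adjusted over the list alone. Scaled by total reads the medians of the stress, NRF2, apoptosis, transport, macrophage, cell cycle and m6A lists were below 0, and with quantile normalization so were those of the NRF2, macrophage, antigen presentation and m6A lists. The p53 list was called, upward, with the stricter filter, and the stress and antigen presentation lists without a filter. T and NK cell markers rose in 4 of 5 tested cases and 1 fell (limma camera adjusted p = 0.52), with CD3D at −0.216 after removal of the GC and length trend. CD3D (0.587) and IL7R (0.323) were not called when scaled by total reads, and the summed share of these markers was lower with nigericin (273 and 318 against 450 and 428 per 1e+06 reads). Both tested B cell markers rose.

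On METTL3 depletion the remaining lists did not pass on the reported settings, with limma camera adjusted p of 0.12 for mitochondrially encoded transcripts (3 of 13 down, 2 adjusted over the list alone), 0.39 for NRF2 genes (3 up, 7 down of 16) and 0.62 for heat shock genes (5 up, 1 down of 18). It was 0.69 for immediate early genes (2 up, 8 down of 31; 3 and 8 adjusted over the list alone), 0.79 for p53 targets (3 up, 7 down of 24; 4 and 7 adjusted over the list alone), and 0.87 for interferon genes (3 up, 6 down of 27), antigen presentation (3 up, 7 down of 17; 4 and 9 adjusted over the list alone) and metallothioneins (1 of 5 down, none adjusted over the list alone). NF-kB genes (3 up, 5 down of 21) gave 0.91, cholesterol genes (7 up, 3 down of 23) 0.53, stress genes (1 up, 1 down of 25) 0.94, and apoptosis regulators (4 up, 6 down of 23), transport genes (5 up, 5 down of 26) and T and NK cell markers (1 up, 2 down of 5) 0.93 each. Scaled by total reads the medians of the NRF2, stress, immediate early, p53, metallothionein, NF-kB, transport and T and NK lists turned from below to above 0. For the inflammasome, interferon and apoptosis lists the median was above 0 and the mean below, and for the transport and the T and NK lists camera gave the direction up with a median below 0. The mitochondrially encoded list was called after removal of the GC and length trend (0.048) and without a filter (0.0074), and adjusted p ran up to 0.98 over its alternatives. The antigen presentation list was called without a filter and the heat shock list with quantile normalization. With the pooled variance, though with none of them called on each gene's own, RSAD2 was up by 1.14 and ISG20 down by 0.79, the quinone reductase NQO1 down by 0.74, HMGCS1 up by 0.73, the survival gene BCL2L1 down by 0.84, and AQP9 up by 0.80 beside AQP3 down by 0.86. HMGCS1 was not called without METTL3-depleted replicate 1 (0.627).

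Normalised totals were 2.14 times higher with nigericin than with LPS. Without the 100 most abundant genes the ratio was still 1.72, so those genes were not the whole source. They took at most 37.2% of the reads in each LPS and nigericin library. With such a share the ratio could not have reached the low bound set for that cause, so no more is drawn from the test. Loss of long transcripts remains open, since the correlation of the nigericin change with transcript length across genes was −0.201, between the values set for and against it. GC content may also take part, as the nigericin change rose by 0.191 per 10 percentage points of GC and the LPS replicates differed by −0.161. A biological fall in the number of transcripts per cell with pyroptosis was not tested, because no external standard was measured here.

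The depletion changes followed GC content and length across genes (Spearman −0.442 and 0.275), and genes are not independent. After removal of that trend 2360 of 3483 calls held in the same direction, a share of 0.678 among calls that rest on pooled variance, which within that limit argues against the trend as the whole cause but leaves open how many of the other calls it made. GC bias between libraries occurs in this series: the largest slope between replicates, in the LPS pair, was 0.955 of the depletion slope of −0.168, above the bound set for such bias. In the groups compared here that ratio was only 0.175, which argues against bias of single libraries and not against a bias shared by both libraries of a group, which cannot be told apart from depletion. A list of 42 genes held splicing factors, with the noncoding MALAT1 and the glycosyltransferase gene OGT among them (41 tested, 15 up, 1 down, 17 up adjusted over the list alone). Its median was 0.267 (limma camera p = 0.00012, p = 0.21 with an estimated correlation). Scaled by total reads it was 0.571, where the median of all genes was 0.263. Without MALAT1 and OGT the median was 0.254 (13 up, 1 down of 39, limma camera p = 0.00044, p = 0.23 with an estimated correlation). Without the trend the full list had a median of 0.164 (12 up, 4 down, limma camera p = 0.016, p = 0.45 with an estimated correlation). A rise of splicing factors is therefore a hypothesis, and the trend could account for part of the list median. Members differed in this: without the trend LUC7L (0.75) was at 0.896 and DDX5 (0.72) at 0.602.

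The opposed nigericin and depletion changes may reflect a weaker nigericin response in depleted cells. Noise of single shared LPS and nigericin libraries as the whole source is argued against by the mean covariance of −0.102 with separate libraries. A bias common to both LPS and nigericin libraries would enter the comparisons with opposite signs and stay in that value. The GC slopes of the changes were opposed (0.191 with nigericin and −0.168 on depletion, per 10 percentage points). The covariance was not recomputed without the GC and length trend, so such a bias stays open. On the deposited scale the 715 genes that moved further from the LPS level argue against a uniformly weaker response as the whole cause. A doubled rate of false calls would give 278, as far as the false call rate under the pooled variance holds. The 715 count signs on that scale only and were not recomputed under other scalings or without the GC and length trend. Scaled by total reads the depletion calls split 3100 up and 973 down, so under those settings a uniformly weaker response stays open. The share of 0.257 passed the bound set against a weaker response by less than its exact interval (24.1% to 27.4%). How far a weaker response accounts for the rest therefore stays open. A different time of harvest or extent of cell death between the groups would also be open, since nigericin was given for 60 to 90 minutes and neither was recorded per library in the labels.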
